A study of Homo sapiens with 4 samples.

How the data were processed

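Total RNA from cultures labelled HT-29, an established human cell line derived from a colorectal adenocarcinoma, was profiled on 4 Illumina HumanHT-12 V4 BeadChip arrays, which measure transcripts with oligonucleotide probes attached to beads. The arrays hold 4 groups of 1 array each, on 2 chips. Chip 1 carried a control and cells treated with cyclopamine, a steroidal alkaloid that blocks the Hedgehog receptor component Smoothened. Chip 2 carried a control and cells treated with GANT61, a small molecule described as an inhibitor of the GLI transcription factors, which act at the end of the Hedgehog pathway. Per the labels both compounds were used at 20 µM for 48 h. The labels of the chip 1 control disagree: its source name gives tomatidine, a steroidal alkaloid related to cyclopamine, whereas its title and treatment give the solvent DMSO. It is called the chip 1 control here, and no result assumes either reading. The chip 2 control is labelled DMSO throughout.

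The deposited intensity tables hold, for each probe and array, the summarised bead intensity on the original scale and a detection p-value. Per the file headers, each p-value column stands to the right of the intensity column of its array. This was checked by rank correlation: intensity and its neighbouring p-value had Spearman rho from -0.992 to -0.988, against -0.917 to -0.898 for the p-value of the other array on the same chip. The deposited series table holds log2 intensity. Its values equalled the log2 of the deposited intensity within 5e-09 on each of the 4 arrays, so it carries no normalisation or background correction beyond that of the intensity tables. The software and settings behind the summarised intensities are not given in the sources used here. The tables of the chips held 47228 and 47229 probes, of which 47227 were on both and were used.

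Median deposited intensity was 90.2 for the chip 1 control, 91.1 for cyclopamine, 72.8 for the chip 2 control and 74.9 for GANT61. At a detection p under 0.01, 13908, 13453, 17068 and 15958 probes were above background on these arrays, in the same order, or 29.4%, 28.5%, 36.1% and 33.8% of probes. With 1 array per group, the number of arrays limits the precision of each value and there is no replicate check of any difference.

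Intensities were background corrected and normalised with neqc of limma 3.58.1 in R 4.3.3, which fits a normal-exponential model to the background inferred from the detection p-values, adds an offset of 16 and quantile normalises, here over all 4 arrays. The offset compresses ratios of dim probes. Probes were assigned to genes with the symbols of the platform annotation, brought up to date through their Entrez identifiers: 30111 probes had 1 symbol, 8 had several and were left out, and 17108 had none. Of the probes with 1 symbol, 30072 matched a current identifier. No genome sequence was used, and no positions are given. Each of 20044 genes was represented by the probe with the highest mean normalised log2 intensity over the 4 arrays. Several array probes of near-identical paralogs (AKR1B and AKR1C enzymes, HSPA1A and HSPA1B, metallothioneins, SAA1 and SAA2, histones, HLA genes) can bind transcripts of a relative, so their symbols are less certain.

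Each treated array was compared with the control of its own chip as a log2 ratio of normalised intensities, over genes with a detection p under 0.01 on at least 1 of the arrays compared. Genes at least 2-fold apart were counted. The controls were compared in the same way, chip 1 minus chip 2, as a yardstick. These comparisons carry no p-value for genes, since no group has more than 1 array. The exception is an alternative, a limma fit that takes the controls of both chips as replicates. The spread of a ratio between different probes of the same gene, each above background on both arrays, served as a measure of technical spread within a comparison. For 2 such probes per gene, the SD of their difference was divided by the square root of 2. The resulting spread is that of 1 probe. It covers neither culture nor labelling. Where 1 array of a pair was below background, its level was replaced by the lowest normalised level of any probe detected on that array, and the resulting fold is given as a lower bound, written as at least N-fold.

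Before the data were examined, 33 lists of genes were written down: Hedgehog pathway components, reported GLI target genes, cholesterol biosynthesis, fatty acid synthesis, cholesterol efflux, lysosome, autophagy, ATF4 and amino acid stress, unfolded protein response chaperones, heat shock, p53 targets, DNA replication, G2 and mitosis, replication-dependent histones, DNA repair, apoptosis regulators, immediate early and MAPK feedback, NF-kB and inflammatory, interferon-stimulated, NRF2 and oxidative stress, metallothioneins and zinc response, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, ribosome biogenesis and MYC targets, WNT targets, colonocyte and enterocyte markers, epithelial mesenchymal transition markers, aryl hydrocarbon and xenobiotic receptor targets, markers of fibroblasts, leukocytes and endothelial cells, and commonly used reference genes. For each list with at least 3 tested members, the members at least 1.5-fold higher or lower were counted, and the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A median below the 2.5th or above the 97.5th percentile is called outside the central 95% of random lists. This percentile describes the arrays at hand: it treats genes as exchangeable, which genes regulated together are not, and it says nothing about how a second culture would behave.

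The genes named were set by a rule, also fixed before the data were examined. Per treated comparison it takes the 12 genes with the largest positive and the 12 with the largest negative log2 ratio whose size exceeded the difference between the control arrays at the same probe. It adds the detected Hedgehog components and GLI targets, and up to 4 members of each list with the largest ratios. Between the compounds it takes the 8 largest differences of log2 ratio in each direction, and the genes at least 2-fold in the same direction with both compounds, up to 10 per direction. The condition on the control difference kept 273 of the 451 genes at least 2-fold apart with cyclopamine and 269 of the 577 with GANT61.

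The steps were tested on simulated data. A copy of each comparison's control array, with 200 detected probes changed, stood in for the treated array. Noise had an SD of 0.15 on the log2 scale for the signal and was smaller for the background. A 3-fold increase was called at 2-fold for 50 of 50 probes in the cyclopamine simulation and 49 of 50 in the GANT61 simulation, and a 3-fold decrease for 49 of 50 and 32 of 50. A 6-fold decrease was called for 50 of 50 and 41 of 50. Among unchanged probes, 1 was called in the cyclopamine simulation and 0 in the GANT61 simulation. The spread per probe in the real comparisons was 0.23 and 0.26, and dim probes had little noise in the simulation. These counts therefore do not give the false calls among dim genes of the real arrays. Of 100 random lists of 20 genes with no added change, 5 lay outside the central 95% with cyclopamine and 4 with GANT61. These lists are random by construction, so the numbers do not give the rate for genes regulated together. With an added 1.2-fold change the numbers were 65 and 57, and with 1.5-fold they were 100 and 100. The code of the limma fit with pooled controls was tested on noise of SD 0.2 around 1 profile, with 200 of 11262 genes shifted by 3 on the log2 scale, and recovered 200 of 200 with 7 false calls. There the controls differed by noise alone, which the real controls do not, so this says nothing about the power of the fit to the real arrays.

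The alternatives, listed before the data were examined, were neqc within each chip, quantile normalisation without background correction, median scaling in place of quantile normalisation, an offset of 50, the series table as deposited, detection on both arrays, detection at p under 0.05, no detection filter, the mean of a gene's detected probes, the mean of both controls, the control of the other chip, thresholds of 1.5-fold and 3-fold, random lists not matched on expression, and the limma fit with both controls as 1 group. Calculations outside R used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Figures were drawn with Matplotlib 3.10.9.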

Results

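Transcript levels were measured in cultures labelled HT-29, an epithelial line from a human colorectal adenocarcinoma, after 48 h with 20 µM cyclopamine, 20 µM GANT61 or a control. The series title presents the compounds as inhibitors of Sonic Hedgehog signalling. Cyclopamine and its control were on chip 1, GANT61 and its control on chip 2, with 1 array for each. Of 20044 genes with a probe, 11262 were above background on at least 1 of the 4 arrays. No group had a second array, so no difference given here has a replicate check, and the values are ratios between single cultures.

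The control arrays of the chips differed in markers of cell type. EPCAM (probe ILMN_2160210), an adhesion molecule of epithelial cells, was at least 142-fold lower in the chip 1 control than in the chip 2 control and was below background on both arrays of chip 1. The same held for LGALS4, an intestinal lectin (at least 99.5-fold lower), KRT19, an epithelial keratin (at least 114-fold), CDH1, the epithelial cadherin (at least 64.1-fold), and CEACAM1, an adhesion molecule of epithelia (at least 37.0-fold). In the other direction VIM, a filament protein of mesenchymal cells, was 41.5-fold higher on chip 1, CCN1, a matrix protein, 53.5-fold higher, and CDH2, the neural cadherin, at least 13.8-fold higher.

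Of 16 colonocyte and enterocyte markers above background on both arrays of chip 2, 12 (75%) were above background on neither array of chip 1, against 1532 of 9370 genes in all (16.4%). The list's median log2 difference, chip 1 minus chip 2, was -2.58, or -1.65 with members below background set to their bounds, and lay below every random list. Exceptions were ALPI, an intestinal alkaline phosphatase, and SPINK4, a goblet cell peptide, at least 61.6-fold and at least 9.0-fold higher on chip 1. Of 23 members tested between the controls, 16 were at least 1.5-fold lower on chip 1, 2 higher and 5 between. The keratin genes KRT8 and KRT18, with DPP4 and MUC13, were above background on at least 1 array of each chip. Epithelial mesenchymal transition markers had a median of 2.86, or 2.41 with bounds, at the 99.99th percentile. Interferon-stimulated genes had a median of -1.87, led by IFI27 (at least 82.2-fold lower on chip 1) and MX1 (at least 23.0-fold lower). LYZ, the lysozyme gene, stood at least 208-fold lower. Of 10905 genes tested, 2079 were at least 2-fold higher and 2546 at least 2-fold lower on chip 1, 42.4% in all. Between different probes of a gene, the SD per probe was 0.55 on the log2 scale (1835 genes). Across all probes, normalised intensities of arrays on the same chip correlated with r of 0.982 and 0.983, and arrays on different chips with r from 0.873 to 0.877. The difference ran through both arrays of each chip. Of 36 colonocyte and enterocyte markers with a probe, 5 were above background in the chip 1 control and 6 with cyclopamine, against 21 in the chip 2 control and 16 with GANT61.

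**Figure D1:**
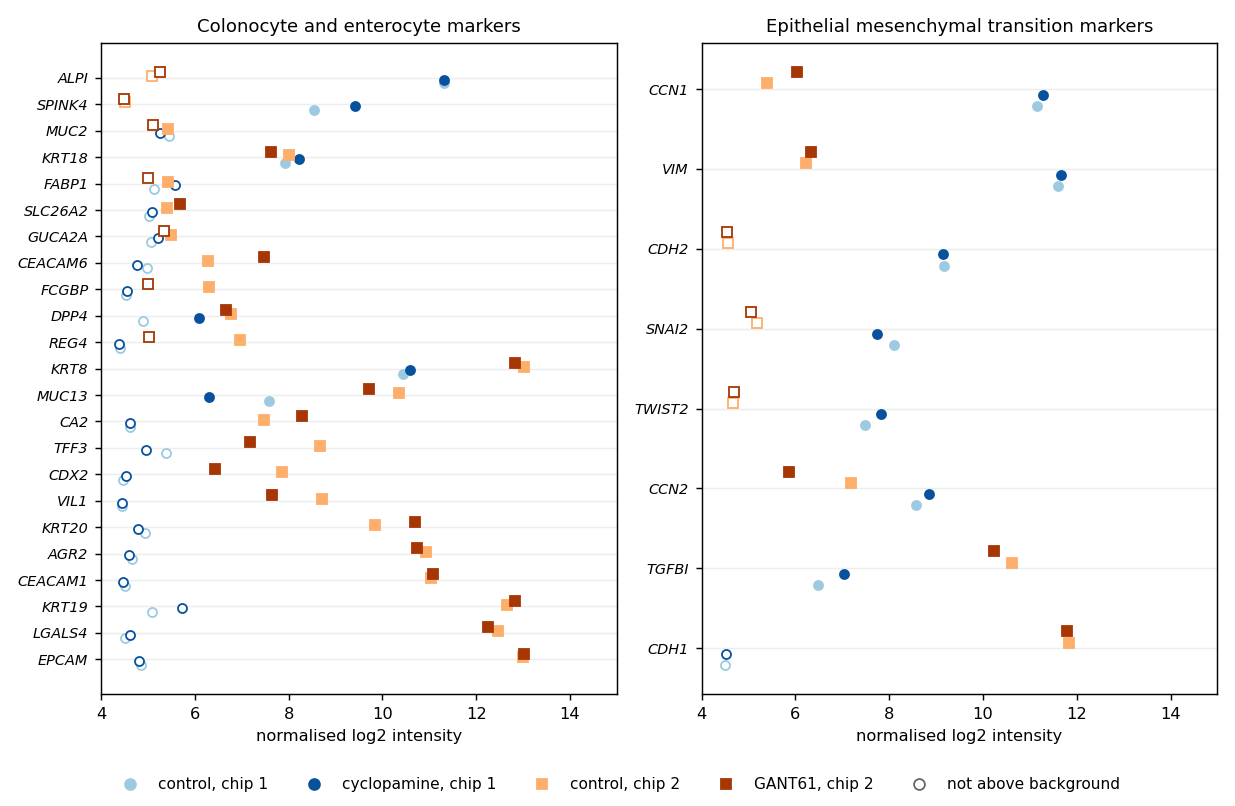
Normalised log2 intensity (horizontal axis) of preset colonocyte and enterocyte markers (left) and epithelial mesenchymal transition markers (right) on each of the 4 arrays, 1 symbol per gene and array, open where the level was not above background. EPCAM, KRT19 and CDH1 are open on both chip 1 arrays and filled on both chip 2 arrays, and VIM is higher on chip 1, whereas ALPI and SPINK4 are above background on chip 1 alone.

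The Hedgehog pathway itself was near or below the limit of the arrays. Of 21 components with a probe, 7 were above background anywhere. SHH, the ligand, PTCH1, its receptor, SMO, the target of cyclopamine, SUFU, and the transcription factors GLI1, GLI2 and GLI3 were above background on none of the 4 arrays, so no change in them was detectable. With cyclopamine 4 components could be tested: DHH, another ligand of the family, was at least 1.86-fold higher, and GAS1, a co-receptor, KIF7, a ciliary kinesin, and STK36, a kinase, had log2 ratios of 0.43, 0.12 and 0.08. Their median was 0.28, at the 81.1st percentile of random lists. With GANT61 the 5 testable components were IHH, a ligand (at least 1.10-fold lower), KIF7 (0.40), IFT88, a protein of ciliary transport (-0.38), STK36 (-0.17) and DISP1, which releases ligand (-0.08), with a median of -0.17 (-0.14 with the bound of IHH) at the 31.3rd percentile.

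Of 28 reported GLI target genes with a probe, 15 were above background on at least 1 array. GLI1, PTCH1, HHIP and BCL2 were on none. With cyclopamine 9 could be tested and their median was 0.04, at the 59.3rd percentile. CCND1, the gene of cyclin D1, had a log2 ratio of 1.52, VEGFA, an angiogenic growth factor, 0.70, JAG2, a Notch ligand, 0.49, MYC 0.15, IGFBP6 0.04, BMI1 -0.09, CCNE1 -0.20, FOXM1, a transcription factor of mitotic genes, -0.35, and FOXF1 -0.59. This median was -0.20 with median scaling and in the series table, where the median of all tested genes was -0.23 and -0.19. With GANT61, 14 could be tested, of which 6 were at least 1.5-fold higher and 1 lower, and the median was 0.37, at the 99.64th percentile. VEGFA stood at 1.69 and IGFBP6, a binding protein of insulin-like growth factors, at 1.53. SPP1, or osteopontin, was at least 1.75-fold higher. ABCG2, a drug efflux pump, had 0.72, JAG2 0.67, MYC 0.64, CCNE1 0.51, BMI1 0.23, IGF2 0.17, CCND1 0.12, BMP4 0.03, CFLAR -0.46, FOXA2 -0.58 and FOXM1 -0.63. The place of this list above the central 95% of random lists was lost when detection was required on both arrays (median 0.23), at a detection p under 0.05 (0.23) and without a detection filter (0.079). VEGFA also belongs to the glycolysis and hypoxia list.

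With cyclopamine, most tested genes of the NF-kB and inflammatory list and of the interferon list were higher than in the chip 1 control. CCL20 (ILMN_1657234), a chemokine for immature dendritic cells and lymphocytes, was at least 63.1-fold higher. CCL5 (ILMN_2098126), a chemokine for T cells and monocytes, was 15.1-fold higher, with log2 ratios of 3.91 and 4.65 at its 2 probes. Of 17 tested NF-kB and inflammatory genes, 16 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 1.59, or 1.43 with bounds, above every random list; over all 25 with a probe it was 1.01. Of 19 interferon-stimulated genes, 15 were at least 1.5-fold higher and 0 lower, with a median of 1.14, or 1.13 with bounds, also above every random list. Above background with cyclopamine alone, and tested only for that reason, were 8 of the 17 NF-kB and 5 of the 19 interferon genes. The 9 and 14 others had medians of 1.43 and 1.14. The sizes depend on the normalisation: in the series table the medians were 0.99 (NF-kB) and 0.70 (interferon), above every random list as well.

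Among the inflammatory genes, CXCL8 (ILMN_2184373), the neutrophil chemokine, was at least 4.41-fold higher and its other probe had a log2 ratio of 0.98. SAA1, an acute phase protein, was at least 4.34-fold higher and TNFAIP3, a feedback inhibitor of NF-kB, at least 3.01-fold. EBI3, a cytokine subunit, was at least 3.98-fold higher, and FOXP3, a transcription factor known from regulatory T cells, at least 4.11-fold. Interferon-stimulated genes included IFI27 (at least 18.9-fold), HERC5, the ligase that attaches ISG15 to proteins (6.37-fold), OASL (at least 2.76-fold), ISG15 itself with a log2 ratio of 2.27 and IFI6 with 2.18. TMEM158 was at least 4.83-fold higher, SERPINE2, a protease inhibitor, 5.49-fold, and ABCG1, a cholesterol exporter, 4.90-fold. On the lower side were CRIP2, a LIM domain protein (at least 5.23-fold lower), and ID2, an inhibitor of helix-loop-helix transcription factors (5.97-fold lower). CLIC3, a chloride channel protein, was at least 3.72-fold lower, TMT1A at least 2.62-fold, NREP at least 2.73-fold, WDR44 at least 2.60-fold, HECTD2 at least 1.95-fold, ADAM9, a membrane protease, at least 1.92-fold and SFT2D3 at least 1.29-fold. TSC22D3, a glucocorticoid-induced leucine zipper protein, was 3.37-fold lower, although its probes ranged from -2.29 to -0.48, TXNIP, which binds thioredoxin, 3.03-fold lower and SNORD31, a small nucleolar RNA, 2.80-fold lower.

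With these lists included, 8 lay above and 4 below the central 95% of random lists with cyclopamine, among 30 with enough members. Immediate early and MAPK feedback genes, which respond to growth factor signalling, had a median of 0.51 at the 100th percentile (0.17 over all 26 with a probe), with 10 of 21 at least 1.5-fold higher and 0 lower: ETV5 was at least 5.58-fold higher, DUSP4, a MAPK phosphatase, at least 1.96-fold, ETV4 had 1.88 and JUN 1.26. Metallothioneins, which bind zinc and copper, had a median of 1.19 over 5 tested members, at the 99.99th percentile, but 0.25 over all 8 with a probe (98.47th percentile), with MT1G at 1.60, MT2A at 1.47 and MT1X at 1.19, while the zinc exporter SLC30A1 had -1.14. ATF4 and amino acid stress genes had a median of 0.28, or 0.26 with bounds (99.95th percentile), with TRIB3, a pseudokinase, at 1.12, STC2 at 0.95, PCK2 at 0.55 and DDIT3, the stress transcription factor CHOP, at -1.05. Lysosomal genes had a median of 0.26 (99.82nd percentile), with SQSTM1 at 0.86, the protease gene CTSB at 0.80 and HEXA, a hexosaminidase, at least 1.32-fold higher. Ribosome biogenesis genes, with a median of 0.17 (98.63rd percentile), and glycolysis and hypoxia genes, with 0.16 (97.9th), had 1 of 24 and 7 of 23 members at least 1.5-fold higher. The latter included ANKRD37 at 1.64, ADM at 1.40, NDRG1 at 1.23 and the glucose transporter gene SLC2A1 at 1.13. These last 2 lists left their place above the central 95% when probes were averaged and when random lists were not matched, glycolysis also without a detection filter and ribosome biogenesis also in the series table. Lysosomal, glycolysis and ribosome biogenesis medians turned negative in the series table (-0.011, -0.082 and -0.10), and the last 2 with median scaling (-0.078 and -0.070). The median of all tested genes was lower still in these settings (-0.19 and -0.23).

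The list medians of mitosis and respiration genes lay below the random lists with cyclopamine, although most members changed by less than 1.5-fold. Of 45 G2 and mitosis genes, 9 were at least 1.5-fold lower and 0 higher, with a median of -0.36 below every random list: PBK, a mitotic kinase, had -1.03, the cyclin gene CCNA2 -0.92, DLGAP5 -0.84 and NDC80, a kinetochore protein, -0.78. Oxidative phosphorylation genes had a median of -0.28, or -0.27 with bounds, below every random list, with 3 of 36 at least 1.5-fold lower, UQCRB at -0.83 and NDUFA9 at -0.61. Replication-dependent histones had a median of -0.38 (0.07th percentile), with H2BC5 at -0.80 and H2AC6 at -0.79 but H2BC8 at 0.68. Unfolded protein response chaperones, which fold proteins in the endoplasmic reticulum, had a median of -0.26 (0.26th percentile), with DNAJC3 at -1.0, MANF at -0.62, HSP90B1 at -0.60 and PDIA4 at -0.49.

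The other lists lay within the central 95% with cyclopamine, some of them only under part of the settings. Their medians were -0.07 for cholesterol biosynthesis, -0.16 for fatty acid synthesis, 0.27 for cholesterol efflux, -0.10 for autophagy, 0.05 for heat shock, 0.18 for p53 targets, -0.13 for DNA replication, -0.06 for DNA repair, 0.10 for apoptosis regulators, -0.14 for NRF2 and oxidative stress, -0.01 for cytosolic ribosomal proteins, 0.15 for WNT targets, 0.23 for 6 colonocyte markers, 0.14 for epithelial mesenchymal transition markers, -0.07 for aryl hydrocarbon and xenobiotic receptor targets and -0.07 for reference genes. DNA replication genes, at percentile 2.99, lay below the central 95% under 7 of the 10 alternatives that kept the same control, with percentiles from 0.12 to 2.48. NRF2 genes lay below it in the series table (1.0), with detection on both arrays (1.3) and without a detection filter (0.43), and p53 targets above it with detection on both arrays (99.98, median 0.39). The p53 median was negative with averaged probes (-0.034, percentile 45.6), median scaling (-0.043) and in the series table (-0.050), and medians of heat shock, apoptosis, WNT and epithelial mesenchymal transition lists also turned negative in the last 2 settings. In those 2 the median of all tested genes was itself negative (-0.23 and -0.19), and the p53 percentile stayed at 95.41 and 95.01. Cytosolic ribosomal proteins lay above the central 95% in the series table (97.83), although their median there was -0.19. In the heat shock list 4 of 14 members were at least 2-fold higher and 0 lower: the chaperone genes HSPA1A and HSPA1B, which share sequence, had 1.73 and 1.64, HSPA6 was at least 2.19-fold higher and DNAJB1 had 1.01. Among single members of other lists, GDF15, a stress cytokine, had 2.28 and CASP9, an apoptotic protease, -1.33. Each was the only member of its list at least 2-fold apart in its direction. Of 18 p53 targets, 2 were at least 2-fold lower, and of 20 apoptosis regulators 2, BID and FADD, were at least 2-fold higher. Fibroblast, leukocyte and endothelial markers had 1 testable gene each: COL1A1 with -0.07, CD68 with 1.75 (other probes down to -0.15) and ENG with -0.15.

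In all, 279 of 8999 genes were at least 2-fold higher and 172 at least 2-fold lower with cyclopamine, 5.01%. Both arrays were above background for 171 of these 451, and another 45 had a bound of at least 2-fold. With neqc within each chip 218 were higher and 93 lower. The count was 141 without background correction, 161 with an offset of 50 and 137 in the series table, and median scaling left 37.3% of calls on the higher side, against 61.9%. Between different probes of a gene, the SD per probe was 0.23 in log2 ratio (1823 genes).

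With GANT61, most tested genes of the NRF2 and oxidative stress, interferon and NF-kB lists were higher than in the chip 2 control, and most of the G2 and mitosis genes and metallothioneins were lower. AKR1C2 (ILMN_2412336), an aldo-keto reductase, was 26.8-fold higher, with 1.00 on the log2 scale at its other probe. DUSP5 (ILMN_1656501), a nuclear phosphatase of ERK, was 21-fold higher, and CCL20 at least 9.91-fold. Of 18 NRF2 and oxidative stress genes 15 were at least 1.5-fold higher, of 23 interferon-stimulated genes 22, and of 14 NF-kB and inflammatory genes 11, with 0 lower in each, and their medians of 1.25, 1.56 and 1.37 lay above every random list. Over all 25 NF-kB and inflammatory genes with a probe the median was 0.36, also above every random list. Of the 14 tested, 5 were above background with GANT61 alone, and the other 9 had a median of 1.44.

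The other aldo-keto reductase genes named were AKR1B10 (15.7-fold higher), AKR1B15 (12.2-fold) and AKR1C4 (9.32-fold), whose symbols are uncertain because their sequences are alike. TXNRD1, a thioredoxin reductase, had a log2 ratio of 2.35 and SRXN1, a sulfiredoxin, 1.94. UCA1 (ILMN_3239254), a long noncoding RNA, was 16.1-fold higher, CXCL8 15-fold, SDCBP2, an adaptor protein, 10.8-fold with 3 probes from 2.61 to 3.43, RNY4, a small Y RNA, 8.30-fold, and CDKN1A, an inhibitor of cyclin-dependent kinases and p53 target, 7.86-fold. TMEM158 was at least 6.07-fold higher. IFI44L had 2.89, OAS2, a sensor of double-stranded RNA, 2.59, MX1, an antiviral GTPase, 2.35 and IFITM1 2.25. IL32 was at least 2.82-fold higher and RELB, an NF-kB subunit, had 1.86. Lower with GANT61 were NUDT1, which degrades oxidised nucleotides (4.59-fold, other probe -0.42), DEPTOR, an inhibitor of mTOR (4.13-fold, other probe -1.79), EDN1, endothelin (3.87-fold), SLC7A2, a transporter of cationic amino acids (3.72-fold), and TYMSOS, a transcript opposite TYMS (3.34-fold). GHDC was 3.16-fold lower, AKAP7, a kinase anchoring protein, 3.04-fold, NOSTRIN 2.69-fold, SELENBP1 2.63-fold, MOB3B at least 2.04-fold, RASL11A at least 2.01-fold and DNAJC22 at least 1.62-fold.

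The ATF4, unfolded protein response, immediate early, heat shock, autophagy and lysosome lists had medians above the random lists with GANT61. ATF4 and amino acid stress genes had a median of 0.84 above every random list, with 12 of 22 at least 1.5-fold higher, DDIT3 at 2.66, ATF3 at 2.41, TRIB3 at 1.95 and the cystine transporter gene SLC7A11 at 1.55. Unfolded protein response chaperones had 0.75 (9 of 16 higher), with DNAJB9 at 2.12, SDF2L1 at 1.37, EDEM1 at 1.31 and HSPA5, the chaperone BiP, at 1.29. Immediate early and MAPK feedback genes had 0.69 (15 of 24 higher), with FOSB at least 3.46-fold higher and DUSP1 at 1.78. Heat shock genes had 0.39 (99.87th percentile), with HSPH1 at 1.10, and autophagy genes 0.38 (99.66th), with GABARAPL1 at 1.86, WIPI1 at 1.62 and ULK1 at 0.97. Lysosomal genes had 0.65 (11 of 18 higher), with SQSTM1, an autophagy receptor, at 1.54, CTSL at 1.35, NPC1, a cholesterol transporter, at 1.16 and NEU1 at 0.91.

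The lists of cholesterol biosynthesis, fatty acid synthesis, and glycolysis and hypoxia also had medians above the random lists with GANT61. Cholesterol biosynthesis genes had a median of 0.64 (9 of 18 at least 1.5-fold higher, 0 lower), with INSIG1, a sterol sensor, at 1.74, HMGCS1, an early enzyme of the pathway, at 1.30, SQLE at 1.16 and MSMO1 at 1.23 but -0.06 at its lowest probe. Fatty acid synthesis genes had 0.74 (6 of 9 higher, 99.93rd percentile), with ACSS2 at 2.34, FASN, fatty acid synthase, at 1.70, ME1 at 1.12 and SCD at 0.89. Glycolysis and hypoxia genes had 0.68 (12 of 21 higher), with ENO2 at 1.60, ADM at 1.54 and NDRG1 at 1.49. Aryl hydrocarbon and xenobiotic receptor targets had 0.78 (99.94th percentile), or 0.23 over all 14 with a probe, with UGT1A6, a glucuronosyltransferase, at 1.54, TIPARP at 1.39 and NQO1 at 0.79, while CYP1B1, a cytochrome, had -1.26.

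Of 46 G2 and mitosis genes, 27 were at least 1.5-fold lower with GANT61 and 0 higher, with a median of -0.75 below every random list. CCNB1, the mitotic cyclin, had -1.11, MAD2L1, a spindle checkpoint protein, -1.09, the proliferation marker MKI67 -1.05 and KIF20A, a mitotic kinesin, -1.02. DNA replication genes had a median of -0.25 (0.04th percentile; 9 of 42 lower), with RRM2, a ribonucleotide reductase subunit, at -1.06, RPA3 at -1.04 and LIG1 at -0.96. DNA repair genes had -0.28, or -0.27 with bounds (0.07th percentile), with H2AX at -0.98. Metallothioneins had -0.99 (-0.74 over all 8 with a probe), below every random list, with 5 of 6 at least 1.5-fold lower: MT1X -1.56, MT1E -1.31, MT1F -1.17 and MT2A -0.81. WNT targets had -0.38 (0.73rd percentile), or -0.23 with bounds, with the intestinal stem cell factor ASCL2 at -2.12, SP5 at least 2.77-fold lower, DKK1, a WNT antagonist, at -1.23 and CD44 at -0.80. Oxidative phosphorylation genes had -0.32 (8 of 36 lower), with NDUFB3 at -0.84, and cytosolic ribosomal proteins -0.16 (0.23rd percentile; 6 of 46 lower), with RPL7 at -0.97 and RPS23 at -0.95.

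Lists within the central 95% with GANT61 were p53 targets (median 0.18), cholesterol efflux (0.35), replication-dependent histones (-0.20, or -0.06 with bounds), apoptosis regulators (0.17), ribosome biogenesis (0.09), colonocyte markers (-0.19, or -0.12 with bounds), epithelial mesenchymal transition markers (-0.06), leukocyte markers (0.06) and reference genes (0.15). Colonocyte markers lay below it without background correction (percentile 1.55) and in the series table (1.36). Without a detection filter p53 targets (99.18) and apoptosis regulators (99.11) lay above it, as p53 targets did at a detection p under 0.05 (97.59) and apoptosis regulators without background correction (97.64). With median scaling both medians were negative (-0.059 and -0.052), as was the median of all tested genes (-0.23). Within the p53 list GDF15 had 2.27 and PHLDA3 1.08, but SESN1 -1.73. Of 21 colonocyte markers 3 were at least 1.5-fold higher and 6 lower, among them REG4, a secreted lectin, at least 2.78-fold lower, TFF3, a goblet cell peptide, at -1.50 and CDX2, an intestinal transcription factor, at -1.44. Fibroblast and endothelial markers had too few members, with POSTN at -0.34, FAP at 0.10 and ENG at -0.56.

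In all, 365 of 10439 genes were at least 2-fold higher and 212 at least 2-fold lower with GANT61, 5.53%, and 21 of 31 lists lay outside the central 95%, 14 above and 7 below. The WNT list, counted below, lay within it when members below background were set to their bounds. Both arrays were above background for 516 of the 577 genes. Between different probes of a gene, the SD per probe was 0.26 in log2 ratio (2343 genes). With neqc within each chip 372 were higher and 231 lower. The count was 330 without background correction, 372 with an offset of 50 and 315 in the series table, and median scaling left 33.8% of calls on the higher side, against 63.3%.

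**Figure D2:**
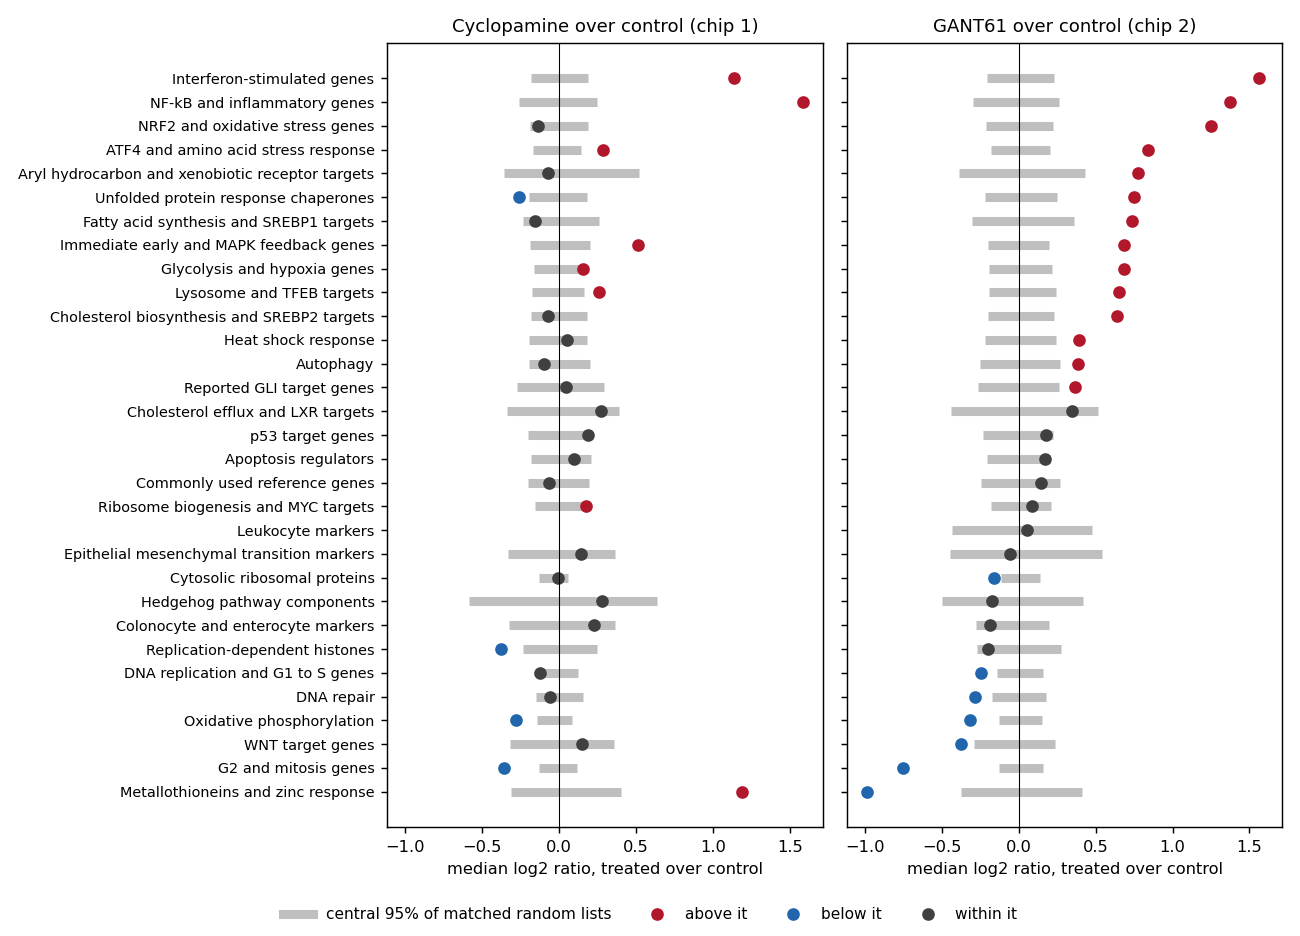
Median log2 ratio of each preset gene list (points) for cyclopamine (left) and GANT61 (right) over the control of the same chip, with grey bars for the central 95% of 10000 expression-matched random lists. NF-kB and interferon lists lie above the bars in both panels, and metallothioneins lie above with cyclopamine (1.19) and below with GANT61 (-0.99).

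The compounds were used at the same dose and time but on different chips, whose control arrays differed in epithelial markers, so a difference between their ratios is also a difference between the cells on the chips. Genes at least 2-fold higher with both numbered 41, against 6.78 for independent lists of the same sizes among 8176 genes tested in both. They were headed by CCL20, CXCL8, TMEM158, SERPINE2 (log2 2.46 with cyclopamine and 2.74 with GANT61) and GDF15 (2.28 and 2.27). LAMP3 followed with 2.06 and 2.15, then IFIT1, an interferon-induced RNA-binding protein, with 1.82 and 2.06, SLCO4A1 with 1.69 and 1.91, RELB with at least 1.95-fold and 1.86, and IFIH1, a sensor of double-stranded RNA, with at least 2.24-fold and 1.56.

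Genes at least 2-fold lower with both numbered 5, against 1.60 for independent lists. They were SSBP3, with -1.23 and -1.23, SESN1, a stress-induced regulator of mTOR signalling (at least 1.52-fold and -1.73), LFNG, a modifier of Notch (at least 1.35-fold and -1.25), DNAJC22 (at least 1.16-fold with cyclopamine) and HMGB3, with no measurable bound with cyclopamine and -1.11 with GANT61. Genes higher with cyclopamine and lower with GANT61 numbered 2, and the reverse 2, against 2.74 and 3.97 for independent lists. Across the 8176 genes the log2 ratios correlated with Pearson r = 0.231 and Spearman rho = 0.198. Genes are not independent replicates, and no control array is shared between the ratios. Without a detection filter r was 0.153.

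Among the genes with the largest difference between the compounds, CCL5 had a log2 ratio of 3.91 with cyclopamine and -0.48 with GANT61. SAA1, FOXP3, TNFAIP3 and EBI3, higher with cyclopamine, were below background on both arrays of chip 2, and AKR1B10, AKR1C4 and AKR1B15, higher with GANT61, were below background on both arrays of chip 1. AKR1C2 was at least 1.14-fold higher with cyclopamine and had 4.74 with GANT61. MT1X had 1.19 with cyclopamine and -1.56 with GANT61, SLC7A2 0.70 and -1.90, and TMEM156 at least 2.26-fold higher and -0.21. DDIT3 had -1.05 and 2.66, UCA1 -0.13 and 4.01, DUSP5 0.88 and 4.39, and ACSL1, an activating enzyme of fatty acids, at least 2.01-fold lower and 2.17. By list, the median difference of log2 ratios, cyclopamine minus GANT61, lay above the random lists for metallothioneins (2.27), G2 and mitosis (0.29) and cytosolic ribosomal proteins (0.18). It lay below for NRF2 (-1.38), unfolded protein response (-1.04), cholesterol biosynthesis (-1.0), aryl hydrocarbon receptor targets (-0.86), fatty acid synthesis (-0.75), immediate early (-0.66), autophagy (-0.60), ATF4 (-0.50), lysosome (-0.41) and GLI targets (-0.40). Interferon-stimulated genes (-0.12, 17.4th percentile) and NF-kB genes (-0.06, 38.6th) lay within. No interval of these differences can be given with 1 array per group.

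**Figure D3:**
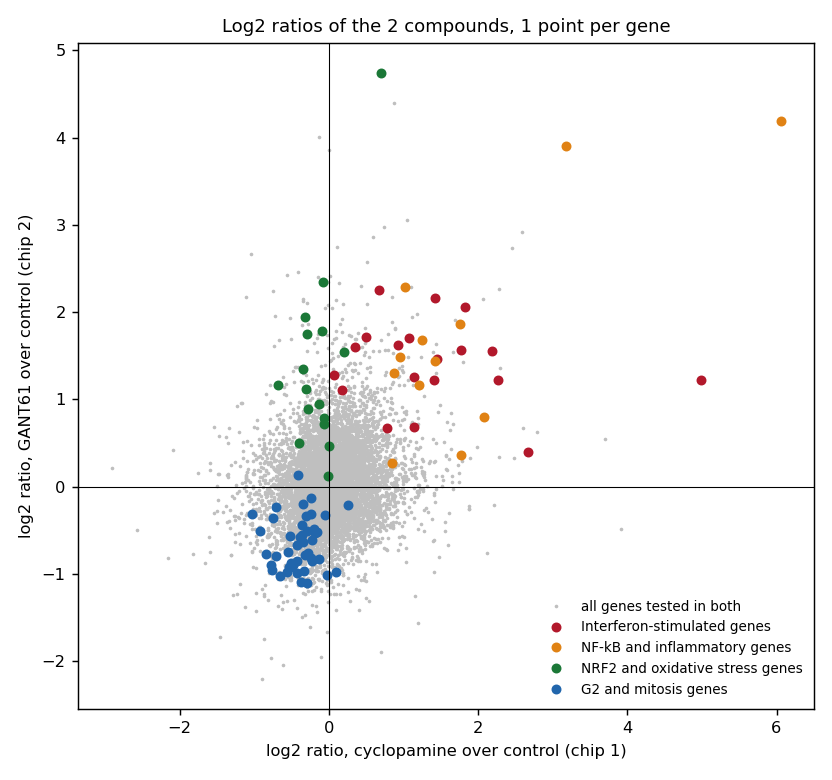
Log2 ratio with GANT61 (vertical axis) against log2 ratio with cyclopamine (horizontal axis), each over the control of its own chip, 1 point per gene tested in both (8176 genes), with 4 preset lists in colour; ratios against a level below background are drawn as fitted, not as bounds. Most interferon-stimulated and NF-kB genes lie to the upper right, NRF2 genes lie high near the vertical axis, and G2 and mitosis genes lie to the lower left.

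A limma fit that treats the controls of both chips as replicates left 0 genes at an adjusted p under 0.05 for cyclopamine and 0 for GANT61, with 13 and 32 genes at an unadjusted p under 0.05 among 11262. That fit has 1 residual degree of freedom, taken from controls that differed by at least 2-fold at 42.4% of genes.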

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

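The tests of the difference between the controls and the test for leukocyte markers were chosen only after the results they bear on were seen. The tests of dim probes, normalisation and near-background members were set before.

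The controls of the 2 chips were at least 2-fold apart for 4625 of 10905 genes. A difference tied to single probes is argued against, since at 2852 genes with 2 detected probes the difference at one probe followed that at the other with r = 0.779 across genes. An effect of tomatidine on the chip 1 control alone is argued against as the source of most of the difference. The treated arrays, neither given tomatidine by its labels, differed between chips with a slope of 0.897 on the control difference (r = 0.913, 11262 genes). A tomatidine effect on top of the difference between chips, or one shared with cyclopamine, was not tested. Of the 16 colonocyte and enterocyte markers above background on both chip 2 arrays, 75% were above background on neither chip 1 array, against 16.4% of all genes, and VIM and CDH2 were higher on chip 1, so a candidate explanation, written as a hypothesis, is that the chip 1 cultures held other cells than the epithelial line of the labels. ALPI and SPINK4 run against a plain loss of intestinal transcripts, and the keratin genes KRT8 and KRT18 were above background on at least 1 array of each chip. An altered state of the same line, a wrong label and other cells were not separated.

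With cyclopamine, 280 of the 451 genes at least 2-fold apart had 1 array below background, so noise of dim probes might account for part of them. Of 14 such genes with another detected probe, 10 (71.4%, exact 95% interval 41.9% to 91.6%) moved the same way at that probe by at least 0.5 on the log2 scale. Among calls with both arrays above background, the other probe did so for 29 of 37 (78.4%). The interval spans both the value set beforehand for noise and that set against it, and the requirement that the whole interval clear the bound was added after the value was seen. Noise and change in these dim genes cannot be told apart with 14 genes.

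Interferon-stimulated genes were higher with both compounds. The normalisation is argued against as the cause of the list's place outside random lists, since over 5 other normalisations and both comparisons the list's lowest percentile among random lists was 100, although its size depends on the choice: the median fell from 1.14 to 0.70 with cyclopamine in the series table and from 1.56 to 1.18 with GANT61. Near-background members are argued against for cyclopamine. Over the 14 of 19 members above background on both arrays, the median was 1.14, and the percentile was again 100. With GANT61 all 23 tested members were above background on both arrays. There the test could only repeat the main result (median 1.56, percentile 100). Of leukocytes in the treated cultures there was little sign: at most 4 of the 11 leukocyte markers were above background on any array. On chip 1 only CD68 was, on both arrays, so cyclopamine brought no newly detected marker. CD68 had a log2 ratio of 1.75 there, with lower ratios at other probes. On chip 2, 4 markers were above background on each array and 3 on both: CD79A was newly detected with GANT61 and another marker was lost. The 5 markers tested with GANT61 had a median of 0.06, at the 59.6th percentile. The numbers above background, 1 and 1 on chip 1 and 4 and 4 on chip 2, give no sign of many leukocytes. A share too small to bring markers above background was not excluded for either compound. A response to the compounds and a difference between single cultures were not tested, so the pattern is not called biological here.

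The metallothionein list had medians of 1.19 over 5 tested members with cyclopamine, where SLC30A1 went the other way (-1.14), and -0.99 over 6 with GANT61, which lie 2.18 apart. Over all 8 members with a probe the medians were closer, 0.25 and -0.74. The list medians of unfolded protein response chaperones, -0.26 with cyclopamine and 0.75 with GANT61, differ by -1.01. Against random lists the median differences per gene, 2.27 and -1.04, lay outside the central 95%, which describes these arrays. Whether either difference exceeds that between cultures was not tested, since each group has 1 array, and the chip and its cells change with the compound. Some probes are in the table of 1 chip only and entered no comparison. Of these, ILMN_1746972 had an intensity of 105.7 with GANT61 (57.6 in its control, detection p-values 0.0013 and 0.617), and ILMN_3247816 had 141.7 with cyclopamine (73.3 in its control, detection p-values 0 and 0.669). Among 17108 probes without a gene symbol, 193 of 3149 above background were at least 2-fold higher with cyclopamine and 89 lower. Of those above background on both arrays, ILMN_3216365 had the highest log2 ratio, 2.23. With GANT61 the numbers were 92 higher and 69 lower of 3935, and the highest above background on both arrays was ILMN_1795963 with 3.43.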

How the results depend on the processing

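Every alternative here was planned before the data were examined, and the cause of a change was not tested unless it is named. No paired analysis of either compound alone was possible because each group has 1 array. Signal over background limits the results: 280 of 451 calls with cyclopamine and 61 of 577 with GANT61 had 1 array below background. Of 333 log2 ratios of genes chosen by the naming rule, 158 were under 2-fold, and 11 of these changed direction under an alternative that kept the control of the same chip, among them MYC, IGFBP6 and STK36 with cyclopamine and CCND1, BMP4 and IGF2 with GANT61. Of the lists outside the central 95%, 12 of 12 (cyclopamine) and 21 of 21 (GANT61) stayed on their side with neqc within each chip, without background correction, with median scaling and with an offset of 50. In the series table, 11 of 12 and 21 of 21 did, and with averaged probes or unmatched random lists 10 of 12 and 21 of 21. The detection alternatives kept 20 of 21 for GANT61, and for cyclopamine 12 of 12 except 11 without a filter. Lists within the central 95% also moved out of it: DNA replication with cyclopamine under 7 of these alternatives, and up to 2 further lists per setting and comparison, among them NRF2, p53 targets and cytosolic ribosomal proteins (cyclopamine) and colonocyte markers, p53 targets and apoptosis regulators (GANT61).

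Without background correction the genes at least 2-fold apart numbered 141 (cyclopamine) and 330 (GANT61), with 78.0% and 73.3% on the higher side. With an offset of 50 they numbered 161 and 372 (75.8% and 71.8% higher). A larger offset, like uncorrected background, shrinks ratios by construction. With neqc within each chip 218 genes were higher and 93 lower with cyclopamine, against 279 and 172, and 372 and 231 with GANT61, against 365 and 212. Of control calls 30.3% were then on the higher side, against 45.0%. Median scaling moved the median log2 ratio of all tested genes to -0.23 for each compound and -0.54 between controls, which by construction puts calls on the lower side: 37.3%, 33.8% and 25.2% were higher. GLI targets then had medians of -0.20 and 0.20, and glycolysis (-0.078) and ribosome biogenesis (-0.070) turned negative with cyclopamine, above the median of all genes. In the series table the median of all genes was -0.19, -0.11 and -0.13. The counts were 137 and 315 (44.5% higher with cyclopamine), GLI medians -0.20 and 0.20, and lysosome (-0.011), glycolysis (-0.082) and ribosome biogenesis (-0.10) turned negative with cyclopamine, again above the median of all genes. They moved by more than that median did, and the cause was not tested.

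With detection on both arrays fewer genes are tested: 171 passed 2-fold with cyclopamine (76.0% higher) and 2764 between controls, and the GLI median with GANT61 was 0.23. It was 0.23 at p under 0.05, and 0.079 without a filter, where r between compounds was 0.153. Thresholds of 1.5-fold gave 1586, 2074 and 6950 genes for cyclopamine, GANT61 and the controls. Those of 3-fold gave 87, 156 and 2463, with 80.5% and 81.4% higher for the compounds. The limma fit with pooled controls gave 0 and 0 at an adjusted p under 0.05, with 13 and 32 at an unadjusted p under 0.05.

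Using the mean of both controls, or the control of the other chip, brings the difference between chips into each ratio by construction. With the mean, 1374 and 1653 genes passed 2-fold and r was -0.428. Hedgehog medians were 1.02 and 0.58, GLI medians 0.65 and 0.96. With cyclopamine the unfolded protein response (0.10), histones (0.61), DDIT3 (0.32), IFIT1 (-0.023), PBK (0.28), CASP9 (0.55) and SLC30A1 (0.23) reversed, and with GANT61 WNT targets (0.12), LFNG (0.35), MSMO1 (-0.0032), CTSL (-0.21), SDF2L1 (-0.11), DUSP1 (-1.90), IL32 (-0.48), MT1E (1.39), MT1F (0.075), ASCL2 (0.015), TFF3 (0.15) and CDX2 (0.26). With the other chip's control, which moved the median of all genes to 0.19 for each compound, 3439 and 3989 genes passed and r was -0.813. Hedgehog medians were 1.02 and 1.24, GLI medians 0.59 and 1.39. With cyclopamine the unfolded protein response (0.66), G2 and mitosis (0.014), histones (1.63), interferon-stimulated genes (-0.74), oxidative phosphorylation (0.082), DDIT3 (1.68), IFIT1 (-1.87), IFIH1 (-0.96), CCND1 (-0.74), PBK (1.58), CASP9 (2.42), BID (-0.89), ETV5 (-0.35), ETV4 (-0.58), JUN (-0.93), IFI27 (-2.13), SLC30A1 (1.60), SLC2A1 (-0.86) and DPP4 (-0.69) reversed. With GANT61 cholesterol biosynthesis (-0.18), the unfolded protein response (-0.41), WNT targets (1.69), DDIT3 (-0.067), SESN1 (0.45), LFNG (1.94), HMGB3 (0.74), HMGCS1 (-0.73), MSMO1 (-1.23), CTSL (-1.77), NPC1 (-0.98), GABARAPL1 (-1.33), ATF3 (-1.74), SLC7A11 (-0.23), SDF2L1 (-1.58), HSPA5 (-0.11), MKI67 (0.57), DUSP1 (-5.57), IL32 (-3.25), IFITM1 (-0.18), MT1E (4.08), MT1F (1.32), ADM (-1.19), ASCL2 (2.15), SP5 (0.64), REG4 (0.61), TFF3 (1.80), CDX2 (1.96), FCGBP (0.47) and TIPARP (-1.15) reversed. List calls kept their side for 8 of 12 and 15 of 21 with the mean, and 6 of 12 and 10 of 21 with the other control.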

Other observations

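The tests in this part were all chosen only after the results they bear on were seen, on gene lists written down before those tests were run.

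Genes of MHC class I antigen presentation, which load peptides for display to T cells, had medians above the random lists with both compounds, with part of the members at least 1.5-fold higher. With GANT61 5 of 10 tested members were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.40: HLA-B had 2.58, the peptide transporter genes TAP1 and TAP2 1.56 and 0.73, HLA-F 0.66 and the immunoproteasome subunit gene PSMB9 0.59, while ERAP2 and PSMB10 had -0.12 and -0.32. With cyclopamine 2 of 11 were at least 1.5-fold higher and 0 lower, also with a median of 0.40, and TAPBP, TAP1, TAP2 and HLA-B had 0.59, 0.59, 0.57 and 0.52. HLA genes are much alike, so the probe for HLA-B can bind relatives. B2M, which another list holds, was left out.

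The hypothesis that the median of MHC class I genes goes higher together with the interferon-stimulated genes was set against random lists. The median lay at the 98.94th percentile with GANT61 and at the 99.84th with cyclopamine, which is consistent with it for each compound. With 1 culture per group it stays a hypothesis.

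Aminoacyl tRNA synthetase genes, several of which are known ATF4 targets, were examined beside the ATF4 list, which was higher with GANT61. Of 18 synthetase genes with a probe, 2 were left out because preset lists already hold them. The ATF4 list names CARS1, GARS1 and WARS1, so synthetases of that list were not tested here. Of the 16 others, all tested, 1 was at least 1.5-fold higher with GANT61 and 0 lower. The median was 0.09, at the 74.68th percentile, so the hypothesis that synthetases outside the ATF4 list move with it did not hold on this test. VARS1 had 0.68 and FARSA 0.57, but KARS1 -0.41. With cyclopamine the median was 0.10, at the 89.72nd percentile, and FARSB had 0.59.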
